A study of Mus musculus with 9 samples.

How the data were processed

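Sorted microglia of 3 genotypes were measured on 9 one-colour arrays, 3 each of wild type, FAD and FAD DKO. Total RNA was amplified and biotin-labelled before hybridisation, per the labels. The deposited values are log2 signals per probe set, made by RMA per the submitters' processing notes, which covers background correction, quantile normalization and summary over probes. The log2 scale was read from the deposited values, which had array medians near 5.4 and no missing value. The software version, summary level and annotation behind RMA are not given in the sources used here. Detection calls and scanner signals were not used here, so signal over background was not analysed, and values near the floor carry little information on a change.

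The value table held 41345 probe sets. A table of probe set names listed 25335 of them; 23521 had 1 gene symbol, 1814 had several, and 16010 were not listed and are unnamed here. Symbols were checked through gene identifiers against the RefSeq table of assembly GRCm38.p6, which matched 23328 of the probe sets with 1 symbol and updated 0 symbols. That table was used for names, gene class and gene order only, and no coordinates are given. Where several probe sets shared a symbol (1082 genes), the one with the highest mean over the 9 arrays stood for the gene, which left 22180 genes for testing. The smallest SD of the difference between any 2 arrays was 0.335 (log2), so no array was a copy of another.

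Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend, not robust), in 1 fit of all 9 arrays with a mean per group, so that the groups share an estimate of the spread. The fit had 6 residual degrees of freedom, and 8.98 after moderation. The contrasts were FAD minus wild type, FAD DKO minus FAD, and FAD DKO minus wild type. P-values are two-sided and adjusted by Benjamini-Hochberg over all genes of a comparison, and a gene was called at an adjusted p under 0.05. Gene lists were tested with camera of limma at a preset correlation of 0.01 between genes, two-sided and adjusted over the lists of a comparison, and again with an estimated correlation. Counts adjusted over the list alone use Benjamini-Hochberg over the measured members of that list. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

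The 27 gene lists were fixed before the data were examined, as were the comparisons, the fit, the rule for named genes and all alternative settings except the last one below. They covered homeostatic microglia, plaque-associated microglia, interferon response, antigen presentation, inflammatory cytokines and NF-kB feedback, phagocytic receptors and complement, lysosome, cholesterol synthesis, cholesterol efflux and lipid handling, glycolysis, oxidative phosphorylation, cell cycle, cyclin-dependent kinase inhibitors, p53 targets and DNA damage, apoptosis regulators, histone deacetylases, HDAC1/2 corepressor complexes, histone acetyltransferases, and immediate early genes and stress of cell isolation. Marker lists stood for neurons, astrocytes, the oligodendrocyte lineage, endothelial and mural cells, perivascular and border macrophages, monocytes and neutrophils, lymphocytes and red cells. The lists hold 653 entries, of which 593 were measured; some genes stand on several lists, and only 2 of 10 red cell genes were measured. The rule named Hdac1, Hdac2 and Cx3cr1, the 10 called genes with the largest change in each direction whose groups did not overlap (leaving out unnamed gene models and small RNA genes), and from each list up to 4 members with the smallest p and any that passed; the text uses a part of these.

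The fit was tested on simulated data with 22180 genes, 200 of them changed, in 5 simulations per comparison. For FAD against wild type it recovered 56.6% of genes changed 1.5-fold, 85.6% of those changed 2-fold and 97.9% of those changed 4-fold, with 5.34% of calls false. For FAD DKO against FAD the shares were 55.3%, 87.8% and 98.4%, with 4.44% of calls false, and for FAD DKO against wild type 60.3%, 88.3% and 97.7%, with 5.34% false. The shares hold for 200 changed genes with independent normal noise. With fewer changed genes the adjusted threshold is stricter, so the shares do not tell how many real changes were called here. A list shifted by 0.2 on the log2 scale was recovered in 5 of 5 simulations of each comparison, at an unadjusted camera p under 0.05 with the preset correlation. As the simulated genes were independent, this does not check list calls among genes that move together. The estimated correlation of the measured lists reached 0.523.

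The alternatives were a filter that kept probe sets with a mean at or above the median of all (5.35), quantile normalization of the deposited values, a trended and robust variance model, only the 2 groups compared, array weights, the mean of a gene's probe sets, every probe set named or not, the replicate number as a block, and leaving out each array in turn. List tests without the genes that stand on more than 1 list were added after the data were seen. The comparisons that share arrays were set beside 100 simulations of fold changes with no effect. Raw array files were not analysed here, and the labels give no batch or scan order, so no batch was tested.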

Results

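Gene expression was measured in microglia, the resident macrophages of the brain, sorted by FACS from female C57Bl/6 mice aged 24 to 28 weeks. There were 3 genotypes with 3 arrays each. Wild type mice were set beside FAD mice, which carry a familial Alzheimer's disease transgene set that leads to amyloid plaques together with floxed Hdac1 and Hdac2 alleles. The third genotype, FAD DKO, carried in addition Cx3cr1CreERT2, a tamoxifen-inducible Cre recombinase knocked into the fractalkine receptor locus and used to delete floxed genes in microglia. Hdac1 and Hdac2 encode class I histone deacetylases, which remove acetyl groups from histones as part of corepressor complexes. All mice received 8 mg tamoxifen at 6 weeks of age, so tamoxifen was common to the groups. The array medians lay between 5.346 and 5.398 and the maxima between 13.81 and 13.94 on the deposited log2 scale. The number of arrays limits the precision, and the median SE of a difference between 2 groups was 0.104 on the log2 scale over 22180 genes. The labels do not state that the arrays of a group come from separate animals, so the p-values measure the spread among samples, which may be technical.

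The targeted genes were read first. Hdac1 stood at 8.44 ± 0.318 in wild type, 8.12 ± 0.086 in FAD and 7.56 ± 0.13 in FAD DKO (log2, SD, n = 3). Its single values were 8.07, 8.65 and 8.60 in wild type, 8.03, 8.14 and 8.19 in FAD, and 7.63, 7.41 and 7.64 in FAD DKO. Hdac2 stood at 8.29 ± 0.086 in wild type, 8.48 ± 0.107 in FAD and 7.80 ± 0.164 in FAD DKO (n = 3). Its single values were 8.28, 8.39 and 8.22 in wild type, 8.56, 8.52 and 8.36 in FAD, and 7.89, 7.61 and 7.90 in FAD DKO. Each FAD DKO array lay below every FAD and wild type array for both genes, so these genes went against no label. The probes may lie outside the deleted part of each gene, in which case they do not check the deletion itself. Cx3cr1, into which the Cre was inserted, stood at 12.20 in wild type, 12.13 in FAD and 11.88 in FAD DKO.

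**Figure D1:**
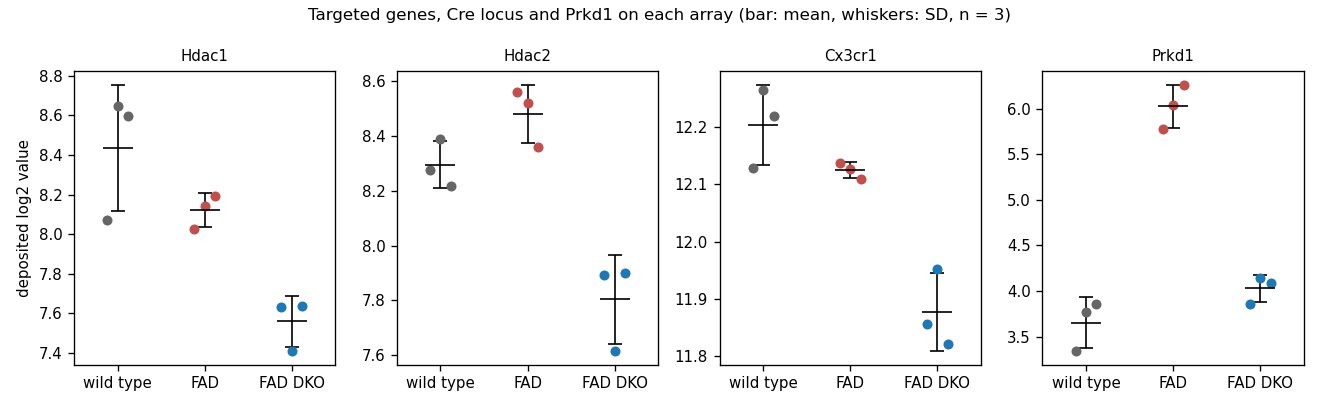
Deposited log2 value (y axis, separate range per panel) of Hdac1, Hdac2, Cx3cr1 and Prkd1 on each array of the wild type, FAD and FAD DKO groups (x axis), with points for arrays, horizontal bars for means and whiskers for the SD (n = 3). Hdac1 and Hdac2 were lowest on the FAD DKO arrays, with means of 7.56 and 7.80, while Prkd1 stood at 6.03 in FAD against 3.65 in wild type and 4.03 in FAD DKO.

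The comparison of FAD with wild type asks how microglia differ in the Alzheimer's disease model when Hdac1 and Hdac2 are not deleted. FAD microglia had far more transcript of Lpl, the lipoprotein lipase that releases fatty acids from triglyceride particles, which rose by 2.98 on the log2 scale (SE 0.164) from 5.67 ± 0.141 to 8.66 ± 0.305 (SD, n = 3). Genes of plaque-associated microglia rose together with it, and genes of glycolysis and of cholesterol synthesis rose by less. Interferon response genes and the genes of homeostatic microglia fell as groups. With an estimated correlation 0 of these lists were called (adjusted p = 0.103 for plaque-associated, glycolysis and homeostatic genes, 0.0828 for cholesterol synthesis and 0.242 for interferon response genes). Prkd1, the serine/threonine kinase protein kinase D1, rose by 2.37 (SE 0.162) from a level of 3.65 to 6.03. Its wild type level lay below the median of all probe sets (5.35), so the size of this change is uncertain.

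In limma, 9 of 22180 genes passed an adjusted p under 0.05, of which 7 rose and 2 fell, and 7 of the 9 changed by at least 2-fold. The adjusted p was 0.000234 for Lpl and 0.00105 for Prkd1. Arsb, the lysosomal arylsulfatase B, rose by 1.44 on the log2 scale (adjusted p = 0.000234), and Myo1e, a myosin of the actin cortex, by 1.56 (adjusted p = 0.00324). Bcl2, which blocks apoptosis, rose by 1.13 (adjusted p = 0.028). Ptchd1 rose by 1.11 and ND3, a mitochondrially encoded subunit of respiratory complex I, by 0.99 (adjusted p = 0.00429 each). Crabp2, a retinoic acid binding protein, fell by 1.97 on the log2 scale (adjusted p = 0.00429); its neighbour Isg20l2 was at -1.05. Gbp7, an interferon-inducible GTPase, fell by 0.82 (adjusted p = 0.0322). Of the 9 calls 7 were kept in each of the 9 fits that left out 1 array, while Bcl2 and Gbp7 were each lost in 7 of these fits. Hdac1 differed by -0.32 (adjusted p = 0.62), Hdac2 by 0.19 (adjusted p = 0.667) and Cx3cr1 by -0.08 (adjusted p = 0.779). Leaving out 1 array moved Hdac1 between -0.50 (without wild type replicate 1) and -0.21 (without wild type replicate 2), Cx3cr1 between -0.12 and -0.05 with the same arrays, and Hdac2 between 0.15 and 0.25. An unadjusted p under 0.05 was reached by 1870 genes (8.43%), and the groups did not overlap for 2624 genes (11.8%), where chance gives 10%.

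Of 35 measured genes of the plaque-associated list, 33 lay above 0, and the list rose with a median log2 change of 0.53 (camera adjusted p = 3.88e-28; adjusted p = 0.103 with an estimated correlation). Over all genes 1 member passed, and 24 rose when adjusted over the list alone. These included Cst7, the protease inhibitor cystatin F (log2 change 2.62, adjusted p = 0.0849 over all genes), and Fabp5, a fatty acid binding protein (2.36, adjusted p = 0.0734 over all genes). The growth factor Igf1 (1.82), the chemokine Ccl6 (1.61), the integrin gene Itgax (1.58) and Apoe, the main lipid carrier of the brain (0.98), were also among them. The homeostatic list fell, with 23 of 25 measured genes below 0 and a median of -0.09 (camera adjusted p = 7.73e-05; adjusted p = 0.103 with an estimated correlation). In limma 0 homeostatic genes passed, over all genes or adjusted over the list alone, and 3 had an unadjusted p under 0.05. Slco2b1, an organic anion transporter, gave -0.20 and Ltc4s, leukotriene C4 synthase, gave -0.30 (adjusted p = 0.312 each over the list alone; Ltc4s was at -0.19 without FAD replicate 1).

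The interferon response list fell with all 26 measured genes below 0 and a median of -0.37 (camera adjusted p = 2.86e-13; adjusted p = 0.242 with an estimated correlation). Adjusted over the list alone, 2 members fell, the antiviral oligoadenylate synthetases Oas2 (-1.06) and Oas3 (-0.38). In limma 0 passed over all genes and 13 had an unadjusted p under 0.05. The wild type arrays were spread widely on this list, with centred list means of 0.60, 0.32 and 0.01, against -0.36, -0.05 and 0.01 in FAD. The median was -0.25 without wild type replicate 1 and the list still fell (camera adjusted p = 1.37e-06).

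Genes of energy and lipid metabolism rose in several lists. Glycolysis had 16 of 20 genes above 0 and a median of 0.15 (camera adjusted p = 2.71e-06; adjusted p = 0.103 with an estimated correlation), with 6 members higher when adjusted over the list alone, and 0 over all genes in limma (6 at an unadjusted p under 0.05). Examples were the glucose transporter Slc2a1 (0.58), the oxygen-responsive transcription factor Hif1a (0.62) and the phosphoglycerate kinase Pgk1 (0.46), each at an adjusted p of 0.00512 over the list alone. Cholesterol synthesis had 16 of 18 genes above 0 and a median of 0.09 (camera adjusted p = 6.74e-05; adjusted p = 0.0828 with an estimated correlation). There 2 members passed over the list alone, the sterol transporter Stard4 (0.54) and the farnesyl diphosphate synthase Fdps (0.46). Cholesterol efflux and lipid handling had 15 of 22 genes above 0 and a median of 0.07 (camera adjusted p = 0.00122; adjusted p = 0.111 with an estimated correlation). Its 4 members that passed over the list alone included Lpl, Fabp5 and Apoe, which the plaque-associated list also holds. Dropping every gene that stands on more than 1 list, an alternative chosen after the data were seen, turned the direction of this list (adjusted p = 0.999). Oxidative phosphorylation rose with 24 of 31 genes above 0 and a median of 0.07 (camera adjusted p = 0.00269; adjusted p = 0.415 with an estimated correlation). The lysosome list rose with 21 of 30 genes and a median of 0.05 (camera adjusted p = 0.00349; adjusted p = 0.698 with an estimated correlation), and was not called without genes that stand on more than 1 list (adjusted p = 0.15).

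The cell cycle list rose, with 25 of 33 genes above 0 and a median of 0.13 (camera adjusted p = 0.000144; adjusted p = 0.18 with an estimated correlation). In limma 0 members passed over the list alone and 5 had an unadjusted p under 0.05, among them the replication helicase subunit Mcm4 at 0.35 (adjusted p = 0.107 over the list alone). Among markers of other cells, monocyte and neutrophil genes rose, with 19 of 21 above 0 and a median of 0.24 (camera adjusted p = 0.00933; adjusted p = 0.698 with an estimated correlation). Astrocyte markers fell, with 11 of 16 below 0 and a median of -0.08 (camera adjusted p = 0.0319; adjusted p = 0.438 with an estimated correlation). The astrocyte transcription factor Sox9 was the 1 member that passed over the list alone (-0.24, adjusted p = 0.0449). The inflammatory list had no common direction (median -0.02, camera adjusted p = 0.97), yet 2 members rose and 4 fell when adjusted over the list alone. The chemokines Ccl3 (0.65) and Ccl4 (0.87) were higher and the chemokine Ccl5 was lower (-1.10). Egr2, an immediate early transcription factor (0.83, adjusted p = 0.000942 over its list alone), and Flt1, a VEGF receptor (0.85, adjusted p = 0.00102 over its list alone), were higher in lists that were not called with all 9 arrays. The immediate early list, which holds Egr2, was called higher without FAD replicate 2 (median 0.09, camera adjusted p = 0.028).

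In all, 11 of 27 lists were called, 8 higher and 3 lower, and 0 with an estimated correlation (lowest adjusted p = 0.0828). The 16 uncalled lists had medians from -0.10 to 0.03 and camera adjusted p from 0.137 to 0.983. They were the inflammatory, antigen presentation, phagocytic receptor and complement, cyclin-dependent kinase inhibitor, p53 target, apoptosis, histone deacetylase, HDAC1/2 corepressor, histone acetyltransferase, immediate early, neuron, oligodendrocyte, endothelial and mural, perivascular macrophage, lymphocyte and red cell lists. Without FAD replicate 2 antigen presentation was called lower (median -0.11, camera adjusted p = 0.00583), and with array weights lymphocyte markers were (median -0.08, 0.0422). The median, mean and test differed in sign in 6 of the uncalled lists, namely phagocytic receptors, apoptosis, HDAC1/2 corepressors, immediate early genes, neurons and oligodendrocytes. Leaving out 1 array ended the call of the astrocyte list (without wild type replicate 1, adjusted p = 0.0619, wild type replicate 3, 0.0767, or FAD replicate 3, 0.19), which was also not called with a low-signal filter (0.297), quantile normalization (0.0922), array weights (0.0571) or these 2 groups alone (0.0507). Leaving out 1 array also ended the call of the monocyte and neutrophil list (without wild type replicate 1, 0.138, or FAD replicate 1, 0.0595). The same held for the lysosome list (without wild type replicate 3, 0.155, or FAD replicate 2, 0.0869) and for oxidative phosphorylation (without FAD replicate 2, 0.0846). The gene count was 33 with a low-signal filter, which did not test Prkd1 as its mean lay below 5.35, 43 with a trended and robust variance model, 22 with array weights and 5 with the arrays of these 2 groups alone.

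**Figure D2:**
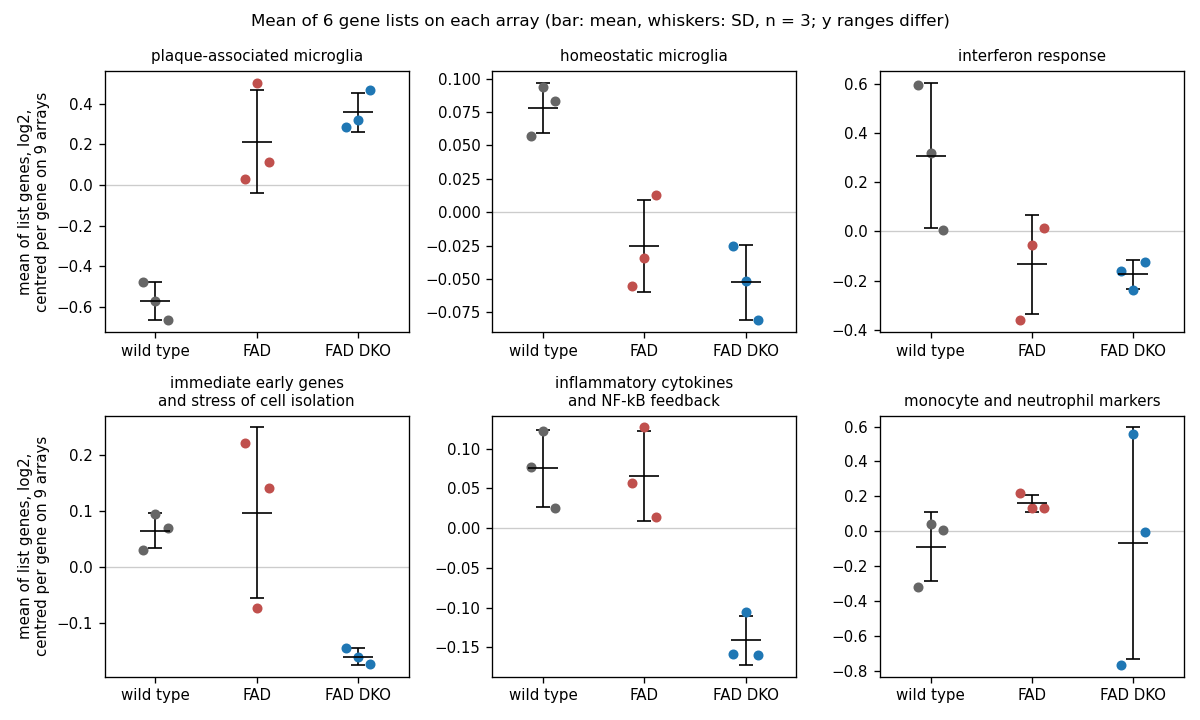
Mean of the genes of 6 lists on each array (y axis, log2, each gene centred on its mean over the 9 arrays, range differs per panel) for wild type, FAD and FAD DKO (x axis); points are arrays, horizontal bars means and whiskers the SD (n = 3). The interferon list spans 0.01 to 0.60 among wild type arrays, and the monocyte and neutrophil list spans -0.77 to 0.56 among FAD DKO arrays.

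The comparison of FAD DKO with FAD asks what deletion of Hdac1 and Hdac2 changes in microglia of the Alzheimer's disease model. The genotypes also differ in Cx3cr1CreERT2. Prkd1, which was high in FAD, fell by 2.00 on the log2 scale (SE 0.162), from 6.03 ± 0.239 to 4.03 ± 0.151 (SD, n = 3). Its FAD DKO level lay below the median of all probe sets (5.35), so the size of this change is uncertain. Immediate early genes such as Atf3, Egr1 and Fosb, and inflammatory genes such as Ccl3 and Nfkbia, fell as groups, though not with an estimated correlation (adjusted p = 0.228 and 0.0668), and of these genes Atf3 alone passed over all genes. The plaque-associated and homeostatic lists were not called with all 9 arrays.

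In limma, 5 of 22180 genes passed an adjusted p under 0.05 and all 5 fell. Besides Prkd1 (adjusted p = 0.0122) they were Atf3, a stress-induced transcription factor (-0.79, SE 0.0838, adjusted p = 0.0315), and Thap6, a zinc finger protein (-0.92, SE 0.102, adjusted p = 0.0363). The small nucleolar RNA gene Snora75 (-1.64, SE 0.149) and the microRNA gene Mir18 (-0.87, SE 0.0756) each had an adjusted p of 0.0122. Leaving out each array in turn ended the calls of Atf3 and Thap6 in 8 of 9 fits, of Snora75 and Mir18 in 4 and of Prkd1 in 3. Of 80 small nucleolar RNA genes, 61 lay below 0. Snora75 and Mir18 lie outside the rule for named genes and are given since the count is small. Prkd1 and Snora75 were the 2 genes with at least a 2-fold change. Neither targeted gene passed over all genes, with Hdac1 at -0.56 (SE 0.147, adjusted p = 0.376) and Hdac2 at -0.68 (SE 0.099, adjusted p = 0.159). Both were lower when adjusted over the list of histone deacetylases alone (adjusted p = 0.0375 and 0.00137). Hdac2 passed over all genes with a low-signal filter (adjusted p = 0.0458) and with a trended and robust variance model (adjusted p = 0.0338). Cx3cr1 was at -0.25 (SE 0.0668, adjusted p = 0.383). An unadjusted p under 0.05 was reached by 1797 genes (8.1%), and the groups did not overlap for 2635 genes (11.9%), where chance gives 10%.

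The list of immediate early genes and stress of cell isolation fell, with 27 of 31 genes below 0 and a median of -0.23 (camera adjusted p = 2.25e-11; adjusted p = 0.228 with an estimated correlation). Over all genes 1 member passed (Atf3), and 11 fell when adjusted over the list alone. Among these were the transcription factors Egr1 (-0.42), Egr2 (-0.61), Fosb (-1.03) and Jun (-0.30), the phosphatase Dusp1 (-0.53), which switches off MAP kinases, and Rgs1 (-0.65), a regulator of G protein signalling. The means of this list ranged more widely among FAD arrays (0.295) than among wild type (0.0634) or FAD DKO arrays (0.029).

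The list of inflammatory cytokines and NF-kB feedback fell, with 23 of 30 genes below 0 and a median of -0.19 (camera adjusted p = 2.26e-07; adjusted p = 0.0668 with an estimated correlation). In limma 0 members passed over all genes, 12 had an unadjusted p under 0.05, and 9 fell when adjusted over the list alone. The chemokines Ccl3 (-0.58, adjusted p = 0.00226 over the list alone) and Ccl4 (-0.72, adjusted p = 0.00591 over the list alone) were lower. So were Nfkbia (-0.47), the inhibitor that holds NF-kB in the cytoplasm, Nfkbiz (-0.54), a nuclear regulator of NF-kB, and Socs3 (-0.69), a suppressor of cytokine signalling, each at an adjusted p of 0.00591 over the list alone. Ccl3 and Ccl4 were higher in FAD than in wild type, and both comparisons use the FAD arrays with opposite sign.

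**Figure D3:**
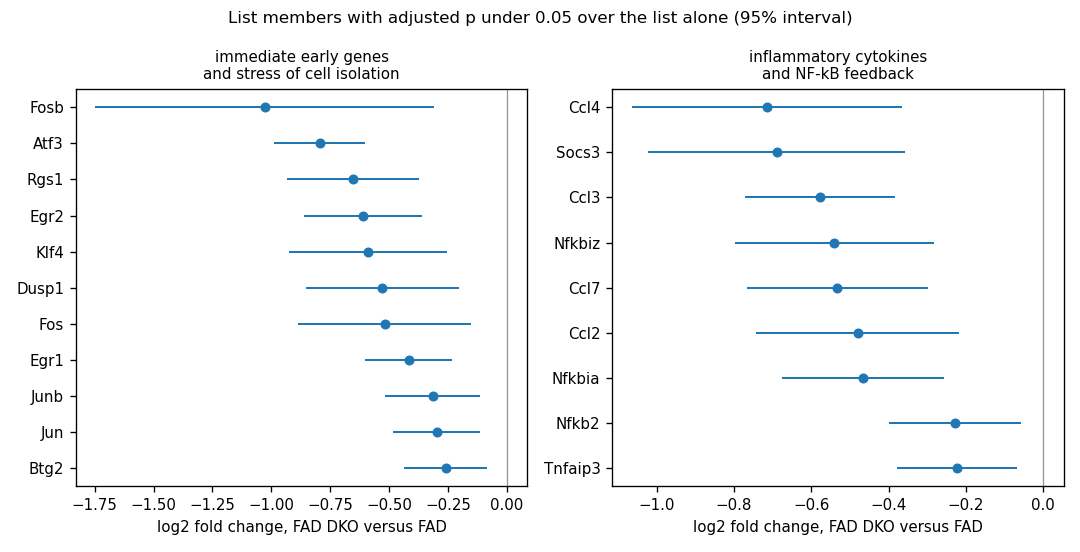
Log2 fold change of FAD DKO against FAD (x axis) with its 95% interval for the 11 genes of the immediate early list and the 9 genes of the inflammatory list (y axis) that had an adjusted p under 0.05 over the list alone; points are limma estimates from 9 arrays and lines the interval. The points lie below 0, from Fosb at -1.03 in the first panel and Ccl4 at -0.72 in the second.

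The cell cycle list fell, with 23 of 33 genes below 0 and a median of -0.02 (camera adjusted p = 0.0224; adjusted p = 0.61 with an estimated correlation). In limma 0 members passed over all genes, 7 had an unadjusted p under 0.05, and the same 7 fell when adjusted over the list alone, among them the replication clamp Pcna (-0.59, adjusted p = 0.0123 over the list alone) and the replication helicase subunits Mcm4 (-0.47) and Mcm6 (-0.85). The call ended without FAD replicate 1 (adjusted p = 0.143), FAD replicate 3 (0.0505), FAD DKO replicate 2 (0.148) or FAD DKO replicate 3 (0.15). In FAD against wild type this list was called higher, and both comparisons use the FAD arrays with opposite sign. In FAD DKO against wild type it was not called (median 0.04, camera adjusted p = 0.577), so the list was not shown to lie below wild type.

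The plaque-associated list was not called with all 9 arrays, and this depended on 1 of them. It had 25 of 35 genes above 0 and a median of 0.06 (camera adjusted p = 0.229). Without FAD replicate 2, the FAD array highest on this list (centred list mean 0.502, beside 0.029 and 0.111), the median was 0.20 and the list was called higher in FAD DKO (camera adjusted p = 2.6e-05). Without FAD replicate 1 the median was 0.01 (camera adjusted p = 0.857), so it moved both ways with single FAD arrays. Its genes included Cst7 at 1.17 (SE 0.397, adjusted p = 0.504), the receptor kinase Axl at 0.57 and Apoe at 0.45, none of which passed over the list alone. Leaving out 1 array moved Cst7 between 0.67 (without FAD replicate 1) and 1.61 (without FAD replicate 2), and Axl between 0.33 and 0.77 with the same arrays. The homeostatic list had a median of -0.00 (camera adjusted p = 0.609), with Tmem119 at 0.29 (adjusted p = 0.572; 0.17 without FAD replicate 1 and 0.43 without FAD replicate 3). The interferon list had a median of -0.01 (camera adjusted p = 0.857), which was -0.11 without FAD replicate 1 (0.143) and 0.02 without FAD replicate 2 (0.882), and antigen presentation a median of 0.18 (camera adjusted p = 0.131); the latter was called higher without FAD replicate 2 (camera adjusted p = 0.00509), without FAD DKO replicate 1 (0.00815) or with a low-signal filter (0.0406). Its median was 0.05 without FAD replicate 1 (0.675) and 0.09 without FAD DKO replicate 2 (0.307). Among chromatin genes, the histone deacetylase list had a median of -0.02 (camera adjusted p = 0.508; -0.06 without FAD DKO replicate 2 and 0.01 without FAD DKO replicate 1). The HDAC1/2 corepressor list had 0.01 (camera adjusted p = 0.868; -0.006 without FAD replicate 2 and 0.02 without FAD DKO replicate 3). The histone acetyltransferase list had 0.03 (camera adjusted p = 0.446; 0.01 without FAD replicate 2 and 0.05 without FAD replicate 1). Cyclin-dependent kinase inhibitors had a median of 0.13 (camera adjusted p = 0.229; 0.22 without FAD DKO replicate 3 and 0.09 without FAD replicate 2), p53 targets -0.01 (camera adjusted p = 0.326; -0.04 without FAD DKO replicate 1) and apoptosis regulators -0.03 (camera adjusted p = 0.177). Monocyte and neutrophil markers had a median of -0.22 (camera adjusted p = 0.0518), with centred list means of -0.77, 0.56 and -0.01 on the FAD DKO arrays. They were called lower without FAD replicate 2 (camera adjusted p = 0.0279) or FAD DKO replicate 2 (2.24e-08), and with quantile normalization (0.0418), array weights (0.000935) or a replicate block (0.0448). Without FAD DKO replicate 1 the direction turned (median 0.12, 0.823), so the sign rested on 1 array. Lymphocyte markers had a median of 0.09 (camera adjusted p = 0.0795), and were called higher without FAD DKO replicate 1 (0.0363), while the median was 0.05 without FAD replicate 2 (0.223) or FAD DKO replicate 2 (0.307).

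Thus 3 of 27 lists were called, all lower, and 0 with an estimated correlation (lowest adjusted p = 0.0668). The 24 uncalled lists had medians from -0.22 to 0.18 and camera adjusted p from 0.0518 to 0.983, and the median, mean and test differed in sign in 4 of them, the phagocytic receptor, oxidative phosphorylation, oligodendrocyte and perivascular macrophage lists. The gene count was 0 in limma without FAD replicate 2 (1683 genes at an unadjusted p under 0.05) or FAD DKO replicate 3 (1799 genes). It was 1 without wild type replicate 3 or FAD DKO replicate 2, 2 without FAD replicate 1 and 3 without wild type replicate 2, so 0 of the 5 genes passed in all 9 fits that left out 1 array. With the 6 arrays of these 2 groups alone it was 0 (1584 genes at an unadjusted p under 0.05), with quantile normalization 3, with a low-signal filter, which did not test Prkd1, 11 and with a trended and robust variance model 12.

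The relation between the 2 comparisons was read on the genes called in FAD against wild type. Both comparisons use the FAD arrays with opposite sign. Of the 9 called genes, Prkd1 was called in the opposite direction in FAD DKO against FAD, where 0.00158 genes are expected of independent lists, a value that leaves out the shared FAD arrays. Adjusted over these 9 genes, which were picked on the shared FAD arrays, Prkd1 (adjusted p = 5.58e-06), Myo1e (-0.55, adjusted p = 0.00758), Bcl2 (-0.53, adjusted p = 0.00758) and Ptchd1 (-0.30, adjusted p = 0.0298) were lower in FAD DKO. Lpl (-0.33, adjusted p = 0.111; -0.16 without FAD replicate 2 and -0.46 without FAD DKO replicate 3) and Gbp7 (0.25, adjusted p = 0.052) did not pass. Picking genes on the shared FAD arrays favours opposite signs, which all 9 genes had, so these adjusted p-values may overstate a return towards wild type. Arsb stood at 11.25 in both FAD groups, against 9.82 in wild type, and Crabp2 stood at 5.52 in FAD and 5.62 in FAD DKO, against 7.49 in wild type. Across genes, which are not independent replicates, the log2 changes of the 2 comparisons had an r of -0.428, beside -0.5 in 100 simulations with no effect and the same shared arrays. The covariance was -0.0126 beside a simulated -0.0104 (SD 0.00029). The simulations held the shared FAD arrays but drew each gene independently. Genes that move together on an array would widen this SD, so it does not measure whether the covariance exceeds that of no effect.

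The comparison of FAD DKO with wild type asks how microglia that carry both the disease transgenes and the deletion differ from normal microglia. Plaque-associated genes rose, led by Cst7 at 3.79 on the log2 scale (SE 0.397), and Ctse, the aspartic protease cathepsin E, rose by 4.04 (SE 0.49, n = 3). Homeostatic, interferon response, inflammatory and immediate early genes fell as groups. With an estimated correlation 0 of these lists were called (adjusted p = 0.102 for plaque-associated and homeostatic genes, 0.2 for interferon, 0.0858 for inflammatory and 0.104 for immediate early genes). Hdac1 was at -0.88 (SE 0.147, adjusted p = 0.0702), Hdac2 at -0.49 (SE 0.099, adjusted p = 0.128) and Cx3cr1 at -0.33 (SE 0.0668, adjusted p = 0.133), and all 3 were lower when adjusted over their lists alone (adjusted p = 0.00384, 0.00703 and 0.0206).

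In limma, 31 of 22180 genes passed an adjusted p under 0.05, 21 higher and 10 lower, and 16 of them changed by at least 2-fold. An unadjusted p under 0.05 was reached by 1805 genes (8.14%), and the groups did not overlap for 2643 genes (11.9%), where chance gives 10%. The plaque-associated list had all 35 measured genes above 0 and a median of 0.54 (camera adjusted p = 1.02e-31; adjusted p = 0.102 with an estimated correlation). Of its members 8 passed over all genes and 23 rose when adjusted over the list alone. They were Cst7 (adjusted p = 0.0152), Lpl (2.65, adjusted p = 0.000652), Fabp5 (2.69, adjusted p = 0.0319) and Itgax (2.17, adjusted p = 0.0319). The others were Ccl6 (1.76), Ch25h (1.72), which hydroxylates cholesterol, Ank (1.47), a pyrophosphate transporter, and Apoe (1.43). Gpnmb, a lysosomal glycoprotein, was at 2.25 (adjusted p = 0.0697 over all genes). Other genes that rose were Ctse (adjusted p = 0.0261) and Egln3, an oxygen-sensing prolyl hydroxylase (1.71, adjusted p = 0.0081). Arsb (1.43), Flt1 (1.26), ND3 (0.96), Ptchd1 (0.81) and Myo1e (adjusted p = 0.0291) rose as well.

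Among the 10 genes that fell were Crabp2 (-1.87, adjusted p = 0.00872), Ccdc122 (-1.02, adjusted p = 0.0261), Trim30c (-0.82), Thap6 (-0.80) and Atf3 (-0.69). Gbp10, an interferon-inducible GTPase (-0.75), the circadian repressor Nr1d1 (-0.67) and Tnfaip3, an inhibitor of NF-kB signalling (-0.49), fell too. The calls of Trim30c, Gbp10 and Tnfaip3 were lost in each of the 9 fits that left out 1 array, that of Nr1d1 in 7 and that of Crabp2 in 4. Snora75, outside the rule for named genes, fell by 1.33 on the log2 scale. The inflammatory list fell, with 22 of 30 genes below 0 and a median of -0.14 (camera adjusted p = 5.55e-07; adjusted p = 0.0858 with an estimated correlation). Over all genes 1 member passed, and 9 fell and 1 rose when adjusted over the list alone. Examples were the chemokine Ccl12 (-0.68, adjusted p = 0.0512 over all genes) and Nfkbia (-0.58, adjusted p = 0.0637). Immediate early genes fell, with 26 of 31 below 0 and a median of -0.19 (camera adjusted p = 1.9e-09; adjusted p = 0.104 with an estimated correlation). Over all genes 1 passed, and 11 fell when adjusted over the list alone, among them Egr1 (-0.44) and Dusp1 (-0.55). The interferon list fell, with all 26 genes below 0 and a median of -0.39 (camera adjusted p = 9.1e-14; adjusted p = 0.2 with an estimated correlation). In limma 4 members fell when adjusted over the list alone, including Cxcl10 (-1.20) and Oas2 (-1.12). The wild type arrays, spread on this list with centred means of 0.60, 0.32 and 0.01, are those compared with FAD. The homeostatic list fell, with 22 of 25 genes below 0 and a median of -0.05 (camera adjusted p = 7.81e-06; adjusted p = 0.102 with an estimated correlation). In limma 5 members fell when adjusted over the list alone, including Cx3cr1 and Crybb1 (-0.52). As the Cre is inserted into Cx3cr1 in the FAD DKO mice, its fall cannot be read as a change of homeostatic genes.

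Metabolic lists rose here too. Glycolysis had 15 of 20 genes above 0 and a median of 0.15 (camera adjusted p = 0.000138; adjusted p = 0.104 with an estimated correlation), with 7 members passing over the list alone, such as Slc2a1 (0.53). Cholesterol efflux and lipid handling had 14 of 22 genes above 0 and a median of 0.07 (camera adjusted p = 0.00201; adjusted p = 0.104 with an estimated correlation). Its 4 called genes were Lpl, Fabp5, Ch25h and Apoe, and without genes that stand on more than 1 list its direction turned (adjusted p = 0.893). Cholesterol synthesis rose with a median of 0.09 (camera adjusted p = 0.013; adjusted p = 0.104 with an estimated correlation). Oxidative phosphorylation rose with a median of 0.10 (camera adjusted p = 0.00424; adjusted p = 0.365 with an estimated correlation) and the lysosome list with 0.04 (camera adjusted p = 0.0177; adjusted p = 0.598 with an estimated correlation; 0.3 without genes that stand on more than 1 list). The scavenger receptor Stab1 (-0.58) was lower when adjusted over the phagocytic receptor list alone (adjusted p = 0.00581), a list that was not called.

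So 10 of 27 lists were called, 6 higher and 4 lower, and 0 with an estimated correlation (lowest adjusted p = 0.0858). The 17 uncalled lists had medians from -0.12 to 0.10 and camera adjusted p from 0.136 to 0.908, and the median, mean and test differed in sign for phagocytic receptors, histone deacetylases and histone acetyltransferases. Monocyte and neutrophil markers were called higher without FAD DKO replicate 1 (median 0.40, camera adjusted p = 0.000445) and lower without FAD DKO replicate 2 (median -0.40, 0.00626). Astrocyte markers were called lower without FAD DKO replicate 2 (0.0245), and apoptosis regulators without wild type replicate 3 (0.0475) or with the mean of probe sets (0.0332). Of the 9 genes called in FAD against wild type, 6 were also called here in the same direction, where 0.00753 are expected of independent lists, a value that leaves out the shared arrays. The wild type arrays serve both comparisons, and part of the excess in this count may come from them. Across genes the log2 changes of these 2 comparisons had an r of 0.573 beside a simulated 0.5, and a covariance of 0.0187 beside a simulated 0.0104 (SD 0.000281). The simulations held the shared arrays but drew each gene independently, so this SD is too small for genes that move together. The gene count was 14, 2 and 8 without wild type replicates 1, 2 and 3, 20 without FAD replicate 3, and 3, 6 and 2 without FAD DKO replicates 1, 2 and 3. Of 24 named calls Arsb and Lpl were kept in all 9 such fits. It was 117 with a low-signal filter (53 higher and 64 lower), 124 with a trended and robust variance model (60 and 64), 82 with array weights (45 and 37), 13 with the arrays of these 2 groups alone (10 and 3) and 14 over every probe set (12 and 2), so the lean to higher genes depended on the setting. The lysosome call ended without wild type replicate 3 (adjusted p = 0.342) or FAD DKO replicate 3 (0.193), oxidative phosphorylation without FAD DKO replicate 3 (0.155) and cholesterol synthesis without FAD DKO replicate 1 (0.112) or with a low-signal filter (0.0953).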

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

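The tests of the small nucleolar RNA class as a whole, of single arrays and of microRNA genes, of the unnamed probe sets, and of explanations for the immediate early list were chosen after these results were seen, while the test of that list and the fits without 1 array were planned.

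Probe sets without a single gene name were left out of the comparisons, and a signal appeared among these 17824 probe sets. In limma over all 41345 probe sets, 4 of them were called in FAD DKO against FAD, all higher, at log2 changes of 1.59, 1.88, 2.38 and 2.11 (adjusted p = 0.027). In FAD DKO against wild type 5 were called, the same 4 at 1.66, 1.92, 2.66 and 2.40 and 1 that carries the names Cmya5 and A630019I02Rik together, at -0.91 (adjusted p = 0.0199). In FAD against wild type 0 were called in limma.

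On the 4 probe sets that were higher, the arrays ranged from 4.47 to 6.26 in wild type, from 4.82 to 6.44 in FAD and from 6.60 to 8.05 in FAD DKO. They may read a transcript that only the FAD DKO mice carry, such as the inserted Cre sequence; this hypothesis needs FAD and wild type to be alike, and their largest difference on the 4 probe sets was 0.283, against a smallest difference of 1.59 between FAD DKO and FAD. A transcript released by loss of Hdac1 and Hdac2 would give the same values, and the 2 cannot be told apart, since the Cre and the deletion go together in these mice. The probe sequences were not used here.

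Other splits of the arrays were compared with the genotypes. For FAD against wild type, 1 of 10 splits of the 6 arrays gave as many genes as the real 9, the real split itself, and the highest of the others gave 0. For FAD DKO against FAD the real split gave 5 genes and the highest other 1, and for FAD DKO against wild type 31 and 0; in each, 1 of 10 splits reached the real count. With 10 splits no share under 0.05 can be reached.

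The immediate early and stress list was lower in FAD DKO than in FAD (median -0.23), a call lost with an estimated correlation (adjusted p = 0.228). With the preset correlation, dependence of the call on 1 array was excluded, since the highest adjusted p over the fits without 1 FAD or FAD DKO array was 6.69e-07. A shift from normalization that depends on level was excluded as the whole cause, since 1296 other genes of the same level had a median of -0.016 (-0.0249 to -0.00923 over the fits without 1 array) while that of the list was -0.23 (-0.297 to -0.206). A change in cell handling stays open, as these genes respond to dissociation and sorting: the list mean ranged over 0.295 among the FAD arrays alone, more than the size of the difference between the genotypes (-0.26), and the labels give no order of isolation. An effect of the loss of Hdac1 and Hdac2, which the design names, also stays open and cannot be told apart from handling here. The same holds for an effect of Cx3cr1CreERT2, which only the FAD DKO mice carry and which goes together with the deletion.

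Small nucleolar RNA genes were lower in FAD DKO than in FAD as a class, with 61 of 80 below 0, a median of -0.14 and, without the called Snora75, a camera p of 2.15e-11 with the preset and 0.00559 with the estimated correlation. With the preset correlation it did not rest on 1 array, as the highest camera p without 1 FAD or FAD DKO array was 5.98e-08. The centred means of the class were -0.0542, -0.233 and -0.119 on the FAD DKO arrays. The lowest of these, replicate 2, also correlated least with the other 8 arrays (mean r 0.9776, where the other arrays had 0.9814 to 0.9831). Lower recovery of all short transcripts alike was excluded as far as the microRNA probe sets read short forms and not longer precursors, since the 138 microRNA genes at or above the median level of all probe sets had a median of 0.0438 (0.0147 to 0.0722). Lower recovery of short RNAs other than microRNAs stays open. Over all levels, 17 such genes (small nuclear, guide, RNase P, Y and telomerase RNA) had a median of -0.22 (bootstrap 95% interval -0.307 to -0.128). The small nucleolar RNA genes had -0.14 (-0.276 to -0.072). At or above the median level the order turned. There 13 other short RNA genes had -0.199 (-0.259 to -0.0334) and 55 small nucleolar RNA genes -0.266 (-0.393 to -0.137). These intervals overlap, so the sets cannot be ranked. Lower output of the host genes stays open, as the 15 Snhg genes had a median of -0.01045 (-0.186 to 0.0359). These 15 were taken by their Snhg symbol. Host genes with other names were not tested, and this median does not speak for them. A biological effect of the deletion or of Cx3cr1CreERT2 on this class was not tested apart from these explanations.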

How the results depend on the processing

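The setting without genes that stand on more than 1 list was chosen after seeing the data. With a low-signal filter, FAD against wild type gave 33 genes (15 at 2-fold or more), FAD DKO against FAD 11, and FAD DKO against wild type 117 (25 at 2-fold); fewer genes were tested there, and of the main calls 8 of 9, 4 of 5 and 28 of 31, as Prkd1 and others lay below the filter. A trended and robust variance model gave 43 (17), 12 and 124 (29) genes, and array weights gave 22 (13) and, in FAD DKO against wild type, 82. With only the 2 groups compared, which leaves fewer arrays for the spread, the counts were 5 (4), 0 in limma (0; 1584 genes at an unadjusted p under 0.05) and 13. Over every probe set, FAD DKO against FAD gave 6 at 2-fold and FAD DKO against wild type 14 in all, and quantile normalization gave 3 genes in FAD DKO against FAD. For the variance model, array weights, probe sets and normalization the cause was not tested. Hdac2 in FAD DKO against FAD stayed at -0.68 and passed with the filter (adjusted p = 0.0458) and the trended model (adjusted p = 0.0338), over a range up to 0.521. The correlation of changes was -0.348 with the filter, for which no simulation with no effect was run. With an estimated correlation 0, 0 and 0 lists were called in camera. Dropping genes that stand on more than 1 list turned the lipid handling list in FAD against wild type (adjusted p = 0.999) and FAD DKO against wild type (adjusted p = 0.893), which then lacked Lpl, Fabp5 and Apoe, and ended the call of the lysosome list in both (adjusted p = 0.15 and 0.3). Lists not called with all arrays gained 18 calls over the settings, 3 in FAD against wild type, 10 in FAD DKO against FAD and 5 in FAD DKO against wild type. Monocyte and neutrophil genes were called in both directions in FAD DKO against wild type, higher without FAD DKO replicate 1 (adjusted p = 0.000445) and lower without FAD DKO replicate 2 (adjusted p = 0.00626).

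Leaving out 1 array gave 8 to 12 genes in FAD against wild type (6 to 8 at 2-fold; 9 to 11 lists), 0 to 5 in FAD DKO against FAD (0 to 4 at 2-fold; 2 to 6 lists) and 2 to 28 in FAD DKO against wild type (2 to 20 at 2-fold; 8 to 12 lists). The range was -0.61 to -0.49 for Hdac1 and -0.74 to -0.58 for Hdac2 in FAD DKO against FAD, and -0.536 to -0.37 for the correlation of changes. Without FAD replicates 1, 2 and 3 this correlation was -0.499, -0.503 and -0.536. No simulation with no effect was run for fewer arrays, so this range has no value to stand beside. Where an array of a group compared is left out, 2 arrays stand for it. In all settings together, named genes kept their direction and side of the threshold in 1311 values, passed newly in 54, lost the call in 228 and reversed in 0; called lists kept both in 383, lost the call in 47 and reversed in 2. The 1311 values include genes that were not called and stayed so. Of the named calls in the 3 comparisons, 7 of 9, 0 of 5 and 2 of 24 were kept in all 9 fits that left out 1 array.

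With the replicate number as a replicate block, the counts were 8, 2 and 11 genes (7 at 2-fold in FAD DKO against wild type), beside 9, 5 and 31 (16), and no list lost its call. The labels do not say that the numbers pair the arrays. Same-numbered arrays had correlations of their deviations from -0.11 to 0.122, with 1 of 9 pairs over 0.1, and 3 of 9 arrays correlated best with their own number. With 3 arrays per group this check is weak, so pairing was neither shown nor excluded.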

Other observations

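The test of neighbouring genes was chosen after the result was seen, as was the count of genes by level described first.

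Highly expressed genes leaned to lower values in FAD DKO than in FAD. Of the 5545 genes with the highest mean level over the 9 arrays, 44 were lower and 1 was higher at an unadjusted limma p under 0.001, while in the other 9 splits of the 6 arrays the larger side held at most 3. Mixed splits carry any genotype difference in their spread, which lowers their counts, and 10 splits allow no share under 0.1. A shift of whole arrays that moves many genes together could give the same counts. Of the 44, 10 stand on a list reported above and 5 are small nucleolar RNA genes; the other 29 lower genes stand beside 1 higher gene, with at most 2 on a side in the other splits. These 29 included Ppan (-0.50) and Gnl3 (-0.57), which act in ribosome production, the transcriptional regulators Id2 (-0.60) and Cited2 (-0.47), the cell cycle kinase Cdk6 (-0.66), the secreted protease Adamts1 (-0.82), the histone demethylase Kdm6b (-0.43), the splicing factor Srsf6 (-0.63), the long noncoding RNA Neat1 (-0.57) and Cln8 (-0.76), all chosen after their values were seen and none called over all genes (adjusted p from 0.149 to 0.241). Upk1b was the 1 higher gene (0.48). In FAD against wild type the same 5545 genes held 41 higher and 10 lower genes, and in FAD DKO against wild type 31 higher and 46 lower.

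Some genes varied widely among arrays of a genotype. The neutrophil calprotectin gene S100a8 stood at 8.63, 11.39 and 10.58 on the FAD DKO arrays, and the neutrophil granule genes Camp (5.95, 9.28 and 8.08) and Ngp (5.58, 8.25 and 7.14) had the same order. The interferon-inducible gene Ifi204 ranged from 6.60 to 8.21 in wild type, from 4.25 to 6.74 in FAD and from 4.29 to 5.90 in FAD DKO.

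A linked haplotype of another strain, which FAD and FAD DKO share and wild type lacks, is a hypothesis prompted by the neighbours Isg20l2 and Crabp2, which fell together. Of the genes shifted in both against wild type (unadjusted p under 0.001 in each), 42 others had a place in the gene order. Among them 1 pair, Abcg3 with Gbp10, lay within 5 genes of each other and moved the same way, against a mean of 0.227 pairs in 10000 random sets (permutation p = 0.204), which leaves the hypothesis open. Neighbours can also share regulation, which this test does not separate.

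A passenger region around the floxed genes was tested on the genes next to Hdac1 and Hdac2: 2 of 80 flanking genes had a p under 0.01 in FAD against wild type (2.5%, against 2.1% of all genes; Fisher's exact test, one-sided, p = 0.503), which gives no excess. Around Cx3cr1, 0 of 40 flanking genes had a limma p under 0.01 in FAD DKO against FAD (2.29% of all genes; Fisher's exact test, one-sided, p = 1).

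Loss of histone deacetylases could release silent genes, which would raise the genes with the lowest level. The median log2 change of the 5545 lowest genes in FAD DKO against FAD was 0.033, and the largest absolute median in the other splits was 0.0283; with 10 splits this leaves the hypothesis open. The next 5545 genes by level had a higher median of 0.0448, so the shift was not specific to the lowest genes, and in FAD DKO against wild type the median of the lowest 5545 was 0.0103. In FAD against wild type the lowest 5545 had a median of -0.025 and the next 5545 of -0.0272, so part of the shift may lie in the shared FAD arrays. The 5545 highest genes went the other way, at -0.0258 in FAD DKO against FAD and 0.0218 in FAD against wild type.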
